A study of Mus musculus with 7 samples.

How the data were processed

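Cytosine methylation was measured by whole-genome bisulfite sequencing, in which bisulfite converts unmethylated cytosines so that they are read as T while methylated cytosines are still read as C. The DNA came from intestinal stem cells of C57BL6/J mice, sorted by flow cytometry for high fluorescence of a green protein made under control of Lgr5, a gene active in the stem cells at the base of intestinal crypts. Per the labels' protocols, each library was made from 10 ng of genomic DNA with the Pico Methyl-Seq kit, which is meant for small amounts of DNA. The letters O and Y in the sample titles were read as old (18 to 26 months) and young (2 months), the ages given in the growth protocol, which left 4 old and 3 young libraries. The titles also carry the letter f, which the labels do not spell out, and the protocol names mice of both sexes.

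The authors deposited, for each library, the count of reads with C and the count of reads with C or T at every CpG site with at least 1 read, per the file headers. Each CpG is listed once, on the plus strand. The submitters' processing notes name FastQC 0.11.5, BSMAP 2.89 and the genome build mm9, without their roles. Read filters, trimming and the treatment of duplicate reads are not given in the sources used here. The deposited ratio, corrected depth and confidence limits were not used here. The deposited counts of the opposite strand served only to recognise sites where a C-to-T variant is likely.

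All levels were computed from the deposited read counts as methylated reads over all reads, in percent, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The depth was 125783700, 141304801, 140497786 and 135113892 reads over CpG sites in old replicates 1 to 4, and 71892281, 61907623 and 66320236 in young replicates 1 to 3. The mean depth per listed site was between 6.66 and 7.42 reads in the old libraries and between 3.57 and 4.06 in the young libraries, too shallow to compare single sites, so that reads were summed over classes of sites and over regions. Per tested 1 kb tile the median was 84 reads in old and 42 in young libraries, and per tested CpG-dense region 405 and 205 reads. Wilson intervals at a confidence level of 95% are given for the mitochondrial level, and they cover counting error only.

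The library was the unit of replication. The labels do not say that each library came from a separate animal, so that permutation p-values measure only the spread between samples, which may be technical. The p-values of the quasi-binomial model below rest also on read counts and on a dispersion shared across regions. Its denominator degrees of freedom were 83.8 for tiles and 15.2 for dense regions, more than 7 libraries alone give. Class levels were compared by a two-sided exact permutation test over all 35 splits of the 7 libraries into 4 and 3, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the classes of a family. Sites were classed by the number of other CpG sites within 50 bp on either side, and tiles by their mean level over all 7 libraries.

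Tiles of 1 kb with at least 3 CpG sites and at least 20 reads in every library were tested, which kept 927104 of 2465142 tiles. CpG-dense regions were runs of sites at most 50 bp apart, with at least 20 sites, at least 200 bp long and with at least 5 sites per 100 bp, defined from the site positions alone. Of 23380 such regions, 21826 had at least 30 reads in every library, with a median length of 514 bp and a median of 43 sites. Methylated and total reads per region were fitted with a quasi-binomial logistic model, whose dispersion was moderated with limma 3.58.1 in R 4.3.3 and held at 1 or above, and old was compared with young by an F test with Benjamini-Hochberg adjustment. A region was called at an adjusted p under 0.05 and a difference of the group means of at least 10 percentage points for tiles or 5 for dense regions. The named regions were the 12 tiles and the 10 dense regions with the greatest difference in each direction, among those called with no overlap between the old and the young libraries.

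These tests, thresholds, classes of sites and tiles, and the rule for named regions were set before the data were examined. Chosen after the data were seen were the classes of dense regions by level, the distance and window comparisons, the groups of neighbouring called regions, the matching of clustered regions by level, the removal of likely variant sites, the spread within groups and every correction for unconverted reads. The correction took either the mitochondrial level or the level at dense regions under 5% as the share of unconverted reads in a library. For the counts of called regions it was run in a pair of forms. A first form subtracted reads and held the counts at 0 or above, and a second, which modelled the share, was chosen as the main form after the counts of the first had been seen. Both forms are given.

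The model was tested on simulated reads drawn at the depths of the real libraries, with 200 regions changed by a known amount. Of the dense regions changed by 10, 20 and 30 points it recovered 35.8%, 77.6% and 90.9%, with 3 false calls among 139. Of the tiles changed by 20, 30 and 40 points it recovered 20.9%, 55.2% and 69.7%, with 4 false calls among 101. Small differences can therefore remain uncalled. The simulation used a fixed spread between libraries, not that of the real data, and gave both groups the same unconverted share. Its rates therefore need not hold for these libraries.

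Alternatives included leaving out each library, a block for the replicate number, other read minimums and region sizes, reads thinned to the shallowest library, edgeR 4.0.16, limma on logit levels, centring each library, no minimum difference, and leaving out very deep or likely variant sites. Promoters, gene bodies, gene lists and the genes planned by name were not analysed here, since the only gene table at hand is of another genome build and no genome sequence was at hand. For the same reason no gene is assigned to any region. Coordinates are those of mm9.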

Results

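DNA methylation was profiled in intestinal stem cells sorted for high Lgr5-driven green fluorescence, from the small intestine of old (n = 4 libraries) and young (n = 3 libraries) mice. Together the 7 libraries read 19940449 CpG sites on the autosomes and the X chromosome, of which 14624491 were read in every library. The old libraries held between 125783700 and 141304801 reads over CpG sites, and the young libraries between 61907623 and 71892281. The Pearson correlation of levels across 1 kb tiles, which are not independent replicates, was 0.943 to 0.948 among old libraries, 0.922 to 0.928 among young libraries and 0.908 to 0.919 between the groups.

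The groups also differed in a measure of unconverted cytosines, which is given first because it moves with age group in every library. Mitochondrial CpG sites, taken here as a measure of reads that escaped conversion, had a level of 2.01% ± 0.281 (SD, n = 4) in old and 6.90% ± 0.677 (SD, n = 3) in young libraries. The lowest young library, replicate 3, was at 6.30% (95% Wilson interval 5.89 to 6.74) and the highest old library, replicate 3, at 2.38% (2.19 to 2.57). The groups did not overlap (two-sided exact permutation p = 0.0286). At the 14550 autosomal CpG-dense regions with a mean level under 5%, the read-weighted level was 1.02% ± 0.0254 (SD, n = 4) in old and 3.01% ± 0.207 (SD, n = 3) in young libraries, again without overlap. Depth differed between the groups in the same complete way, so that age, depth and the unconverted share cannot be separated by leaving out libraries.

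The first comparison asks whether the overall level of CpG methylation in these stem cells differs with age. Over all autosomal sites it was 68.5% ± 0.514 (SD, n = 4) in old and 69.2% ± 0.476 (SD, n = 3) in young libraries. The difference was -0.754 percentage points, and the groups overlapped (two-sided exact permutation p = 0.143). Over the 1525980 sites with at least 5 reads in every library it was -1.44 points equally weighted and -1.85 points weighted by reads. Over those with at least 10 reads, only 14960 of the 19152402 autosomal sites, it was 2.74 points, of opposite sign. None of these had overlap (two-sided exact permutation p = 0.0286). After each library was corrected for its mitochondrial level it was 0.886 points. It was -0.124 points after correction for the level at dense regions under 5%. Both had overlap.

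Beneath the similar overall level, sites with few and with many CpG neighbours differed in opposite directions. Isolated sites, with no other CpG site within 50 bp, were less methylated in old libraries, at 72.4% ± 0.712 (SD, n = 4) against 75.3% ± 0.652 (SD, n = 3). Sites with 6 or more neighbours were more methylated in old libraries, at 20.1% ± 0.265 (SD, n = 4) against 17.7% ± 0.163 (SD, n = 3). Sites with 3 to 5 neighbours were also higher, at 69.8% ± 0.423 (SD, n = 4) against 68.7% ± 0.369 (SD, n = 3). In each of these 3 classes the groups did not overlap (two-sided exact permutation p = 0.0286, Benjamini-Hochberg p = 0.0381 over 4 classes). With all libraries thinned to the reads of the shallowest the differences were about the same, but all 3 classes missed the adjusted threshold (exact permutation, Benjamini-Hochberg p = 0.0571, 0.0571 and 0.0762 for isolated sites, 6 or more and 3 to 5 neighbours). Sites with 1 to 2 neighbours were at 75.3% in old and 76.2% in young libraries (exact permutation p = 0.0857) and overlapped. The gain in the denser classes depended on which sites were counted: over sites with at least 5 reads in every library, equally weighted, the difference was -0.199 points with 6 or more neighbours and -0.567 points with 3 to 5. Over all sites of these classes the differences were 6.82 and 2.88 points after correction for the mitochondrial level (exact permutation, Benjamini-Hochberg p = 0.0571 for both). They were 4.08 and 1.83 points after correction for the level at dense regions under 5% (exact permutation, Benjamini-Hochberg p = 0.0381 for both). At isolated sites with at least 5 reads in every library the difference was -2.80 points, without overlap (two-sided exact permutation p = 0.0286), but missed the adjusted threshold (Benjamini-Hochberg p = 0.0571). Over all isolated sites, corrected for the mitochondrial level, it was -1.61 points, with overlap of the groups. After correction for the level at dense regions under 5% it was -2.39 points, without overlap (two-sided exact permutation p = 0.0286, Benjamini-Hochberg p = 0.0381).

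**Figure D1:**
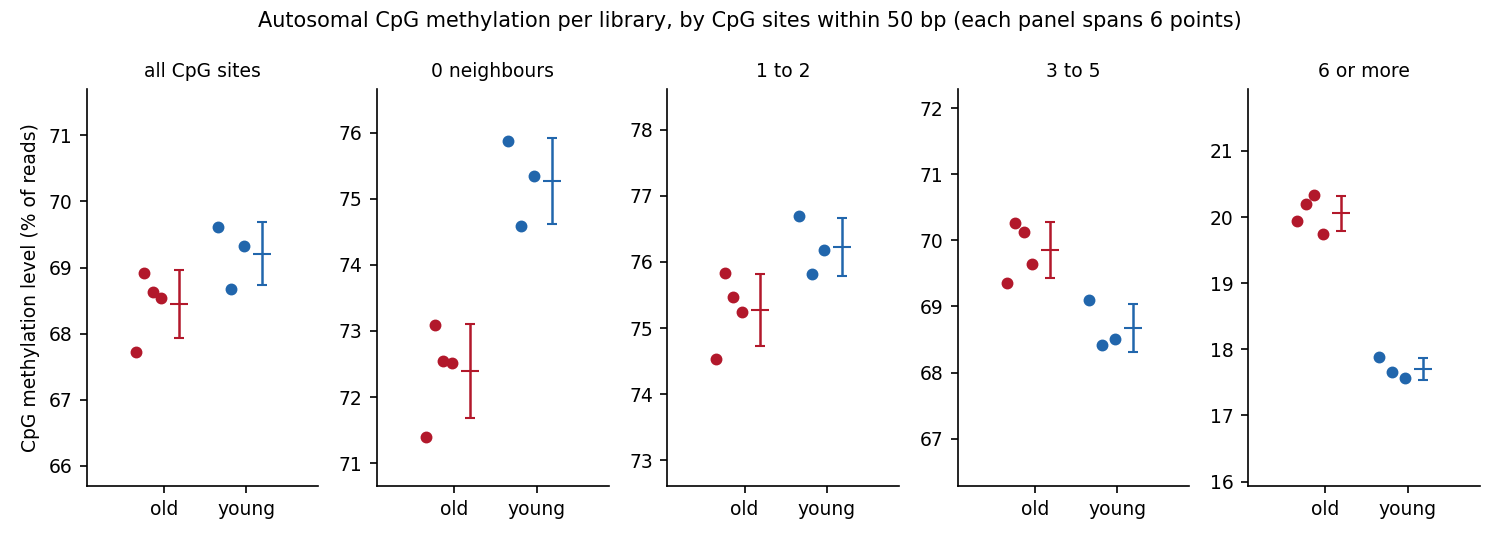
Autosomal CpG methylation level (y axis, percent of reads, each panel spanning 6 points) for all sites and for sites with 0, 1 to 2, 3 to 5 and 6 or more other CpG sites within 50 bp. Each point is a library, and the bars give the mean and SD of the 4 old and 3 young libraries; all old libraries lie below all young ones at isolated sites (72.4% against 75.3%) and above them at sites with 6 or more neighbours (20.1% against 17.7%).

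Autosomal 1 kb tiles of low and intermediate level were lower in old libraries, while highly methylated tiles were close. Tiles with a mean level under 10% were at 2.38% ± 0.0799 (SD, n = 4) in old and 4.39% ± 0.151 (SD, n = 3) in young libraries. Tiles at 10 to 50% were at 29.1% ± 0.767 (SD, n = 4) against 31.2% ± 0.459 (SD, n = 3), and tiles at 50 to 80% were at 68.4% ± 0.933 (SD, n = 4) against 70.7% ± 0.606 (SD, n = 3). The 505346 tiles at 80% or more were at 88.3% and 88.6% (exact permutation p = 0.371). None of the 4 classes passed after adjustment (two-sided exact permutation, Benjamini-Hochberg p = 0.0762 for the lower 3). With equal weight per tile these 3 passed, with differences of -2.42, -3.82 and -2.61 points (two-sided exact permutation, Benjamini-Hochberg p = 0.0381). After correction for the mitochondrial level the difference in the class under 10% was 3.07 points and that in the class of 10 to 50% was 1.55 points, both of opposite sign. In the class under 10% this correction put the young libraries below 0, at -2.70% on average, and so removed too much. With the level at dense regions under 5% instead, the differences were -0.0566 and -0.699 points, with overlap. In the class of 50 to 80% the difference was -0.735 points with the mitochondrial level and -1.68 points with the level at dense regions under 5%. Both had overlap (exact permutation p = 0.314 and 0.0857).

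CpG-dense regions differed by their level. The 1289 autosomal regions with a mean level of 10 to 25% were at 19.6% ± 1.70 (SD, n = 4) in old libraries and at 9.95% ± 0.310 (SD, n = 3) in young ones. The 1056 regions at 25 to 75% were at 54.9% ± 1.93 (SD, n = 4) against 38.7% ± 0.748 (SD, n = 3), and the 2943 regions at 75% or more were at 90.8% ± 0.242 (SD, n = 4) against 88.0% ± 0.162 (SD, n = 3). The 14550 regions under 5% went the other way, at 1.05% ± 0.0262 (SD, n = 4) against 3.04% ± 0.211 (SD, n = 3), and this is the class in which the unconverted share weighs most. Its difference of -1.99 points became 3.17 after correction for the mitochondrial level, which put both groups below 0. The correction for its own level left -0.0034 points by construction. As deposited, the groups did not overlap in these 4 classes (two-sided exact permutation p = 0.0286, Benjamini-Hochberg p = 0.0357 over 5 classes). The 1324 regions at 5 to 10% were at 7.93% ± 0.658 (SD, n = 4) against 6.19% ± 0.240 (SD, n = 3), also without overlap, but did not pass (two-sided exact permutation p = 0.0571). Over all 21162 autosomal dense regions together the levels were 17.8% and 17.3%, and the groups overlapped (exact permutation p = 0.0857). The difference of 0.520 points became 4.97 after correction for the mitochondrial level and 2.24 after correction for the level at regions under 5%, both without overlap (exact permutation p = 0.0286). The classes were chosen after the data were seen and rest on the mean of all 7 libraries.

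**Figure D2:**
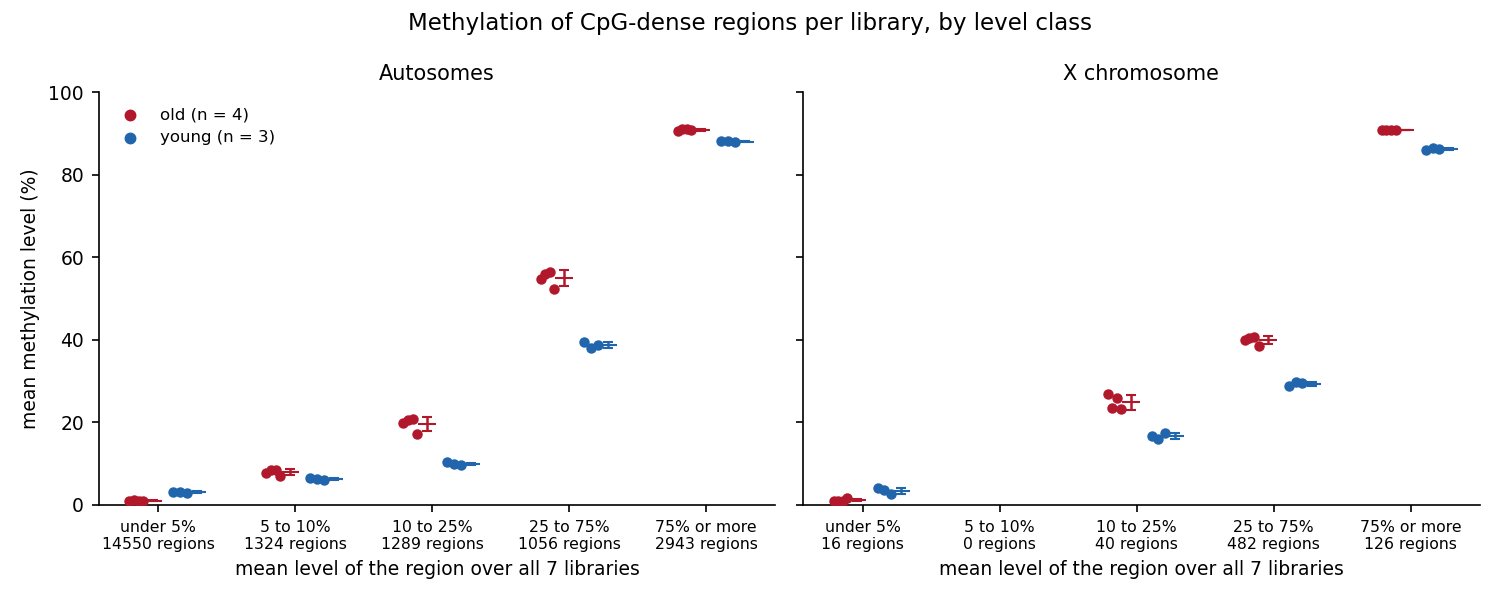
Mean methylation level (y axis, percent) of CpG-dense regions per library, by the region's mean level over all 7 libraries (x axis), on autosomes and on the X chromosome. Points are libraries and bars the mean and SD of old (n = 4) and young (n = 3); the groups are farthest apart among autosomal regions at 25 to 75% (54.9% against 38.7%).

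Tested one by one, 2857 of 21826 CpG-dense regions were called between old and young, 2517 of them higher in old libraries and 340 lower. The groups did not overlap in 12868 of the tested regions, where chance gives 5.71% of them, and 2539 of these were called. The median difference of the 12868 was -2.01 points, close to the -1.99 points at autosomal regions under 5%, where the unconverted share weighs most. Among the 2242 autosomal regions called higher, the median level was 12.6% in young and 35.5% in old libraries, and the median gain was 13.5 points. Of these, 987 were under 10% in young libraries, 629 differed by at least 20 points and 260 by at least 30. The 338 autosomal regions called lower had a median level of 10.1% in young and 1.64% in old libraries, and 249 of them were under 10% in old libraries. The median size of their difference was 7.16 points. By level, 67.9% of the autosomal regions at 10 to 25% and 63.3% of those at 25 to 75% were called higher, but none of those under 5%, of which 151 were called lower. The class under 5% is set by the mean of all 7 libraries and a call needs 5 points, which leaves little room for a gain. The absence of gains there thus does not show that gain depends on level. The count depended on the correction for unconverted reads: with the mitochondrial level modelled, 1530 regions were called higher and 28 lower. With the level at dense regions under 5% modelled, 2486 were called higher and 126 lower. The mitochondrial correction moved the mean difference of the 340 regions called lower as deposited from -10.7 to -6.98 points. That of the 2517 called higher went from 16.6 to 20.7 points, a rise built into the correction, and the 1095 of them that lost the call lost it by adjusted p. Without a minimum difference 12874 regions passed, of which 10140 were lower in old libraries.

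The X chromosome held the greatest share of regions called higher. Of 664 X-linked dense regions, 275 (41.4%) were called higher in old libraries and 2 lower. Their mean level was 47.7% ± 0.783 (SD, n = 4) in old and 38.8% ± 0.322 (SD, n = 3) in young libraries, without overlap (two-sided exact permutation p = 0.0286). The 482 X-linked regions at 25 to 75% were at 39.9% ± 0.987 (SD, n = 4) against 29.3% ± 0.413 (SD, n = 3). This level was planned to bear on the letter f in the titles, since an inactive X chromosome is methylated at dense regions. Of the X-linked regions 482 of 664 lay at 25 to 75%, against 1056 of 21162 autosomal ones, as an inactive X chromosome would give. The sex of the mice was not tested on its own. On the autosomes the share called higher was between 7.32% on chromosome 16 and 19.3% on chromosome 18, with chromosome 12 next at 15.4%. Most X-linked dense regions lie at 25 to 75%, a class that was also called often on the autosomes, so that the share per chromosome does not compare regions of like level. The groups also differed in reads on the sex chromosomes: reads per site on the X chromosome over those on the autosomes were 0.780 to 0.810 in old and 0.720 to 0.746 in young libraries. The Y chromosome took 46.6 to 49.0 of every 1000000 reads in old and 53.8 to 56.6 in young libraries.

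**Figure D3:**
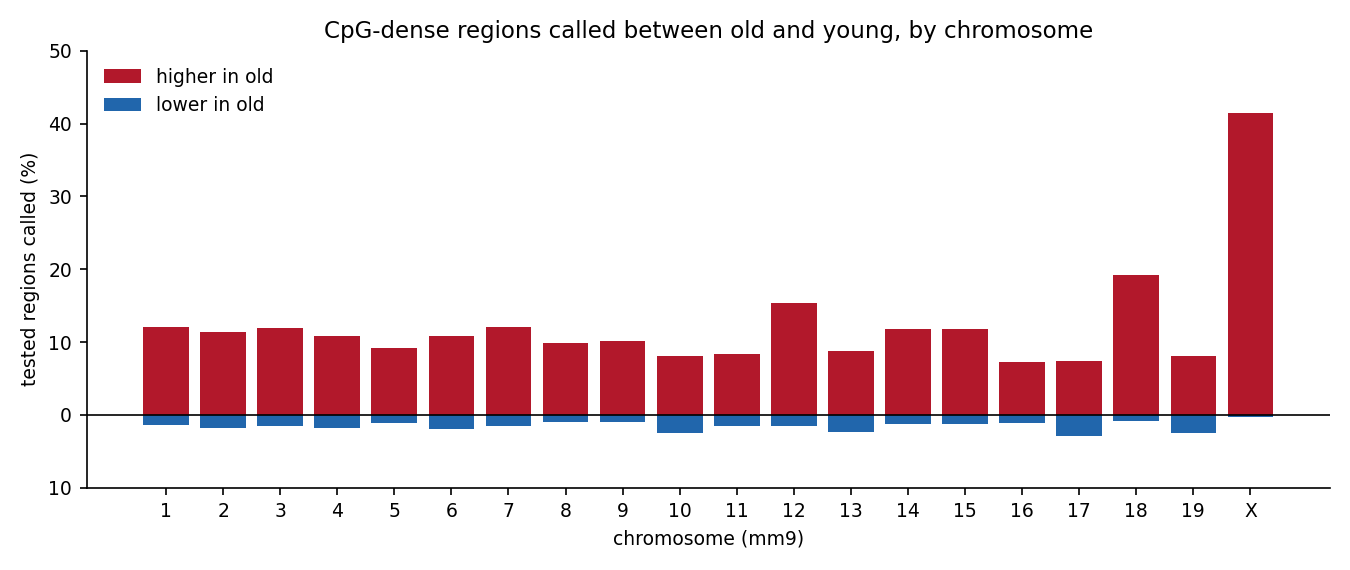
Share of the tested CpG-dense regions called higher (bars above 0) or lower (bars below 0) in old libraries, in percent (y axis), by chromosome (x axis, mm9). The X chromosome has 41.4% called higher, and among the autosomes chromosome 18 has the greatest share (19.3%).

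The dense region with the greatest gain, on chromosome 8 from 87308031 to 87309077 with 80 CpG sites, was at 84.7% ± 4.06 (SD, n = 4) in old and 12.6% ± 3.54 (SD, n = 3) in young libraries (adjusted p = 5.06e-10, quasi-binomial model with limma). The region on chromosome 12 from 22810955 to 22811848 was at 75.2% ± 2.55 (SD, n = 4) against 15.9% ± 1.23 (SD, n = 3), and the region on chromosome 19 from 37761484 to 37761804 was at 85.1% ± 2.32 (SD, n = 4) against 22.7% ± 1.62 (SD, n = 3). A pair of neighbouring regions on chromosome 15, from 87374304 to 87374964 and from 87375023 to 87375736, rose from 6.45% to 61.2% and from 11.6% to 66.7%. The other 5 named gains lay on chromosome 3 from 55584129 to 55584603, chromosome 8 from 107783470 to 107783915, chromosome 17 from 26575622 to 26576318, chromosome 12 from 22990378 to 22990830 and chromosome 4 from 127665272 to 127665610, with old levels of 66.4% to 82.5% and young levels of 12.9% to 27.5%.

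Named losses included regions that were methylated in young libraries and close to 0 in old ones. On chromosome 19 from 7291790 to 7292189 the level was 0.517% ± 0.219 (SD, n = 4) in old and 53.0% ± 4.86 (SD, n = 3) in young libraries (adjusted p = 4.45e-11, quasi-binomial model with limma). On chromosome 6 from 133055262 to 133055764 it was 0.550% against 36.3%. On chromosome 13 from 21813980 to 21814352 it was 0.542% against 39.5%, on the same chromosome from 23673480 to 23673785 it differed by -35.1 points, and on chromosome 12 from 78608643 to 78609140 it was 2.70% against 48.6%. The greatest loss, on chromosome 10 from 98572056 to 98572483, was from 90.7% ± 8.58 (SD, n = 3) in young to 26.0% ± 9.67 (SD, n = 4) in old libraries. Old libraries were less alike at the regions on chromosome 4 from 43505662 to 43505950 (32.1% ± 21.4, SD, n = 4, against 91.2%), chromosome 14 from 51427086 to 51427894 (22.3% ± 14.7, SD, n = 4, against 68.5%) and chromosome 2 from 173595294 to 173596023 (30.7% ± 14.6, SD, n = 4, against 76.6%). The region on chromosome 14 was no longer called with the mitochondrial level subtracted from the reads (adjusted p = 0.0687, quasi-binomial model with limma) or the level at dense regions under 5% subtracted (adjusted p = 0.0556), with differences of -45.4 and -46.1 points. The region on chromosome 11 from 5906339 to 5906908, at 42.6% against 85.8% with as few as 33 reads in a library, was no longer called after correction for the mitochondrial level (adjusted p = 0.0721, quasi-binomial model with limma), although its difference stayed at -43.3 points, against -43.2 before. It also lost the call with the mitochondrial level or the level at dense regions under 5% subtracted from the reads (adjusted p = 0.121 and 0.0865, quasi-binomial model with limma), at -43.5 and -43.8 points.

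**Figure D4:**
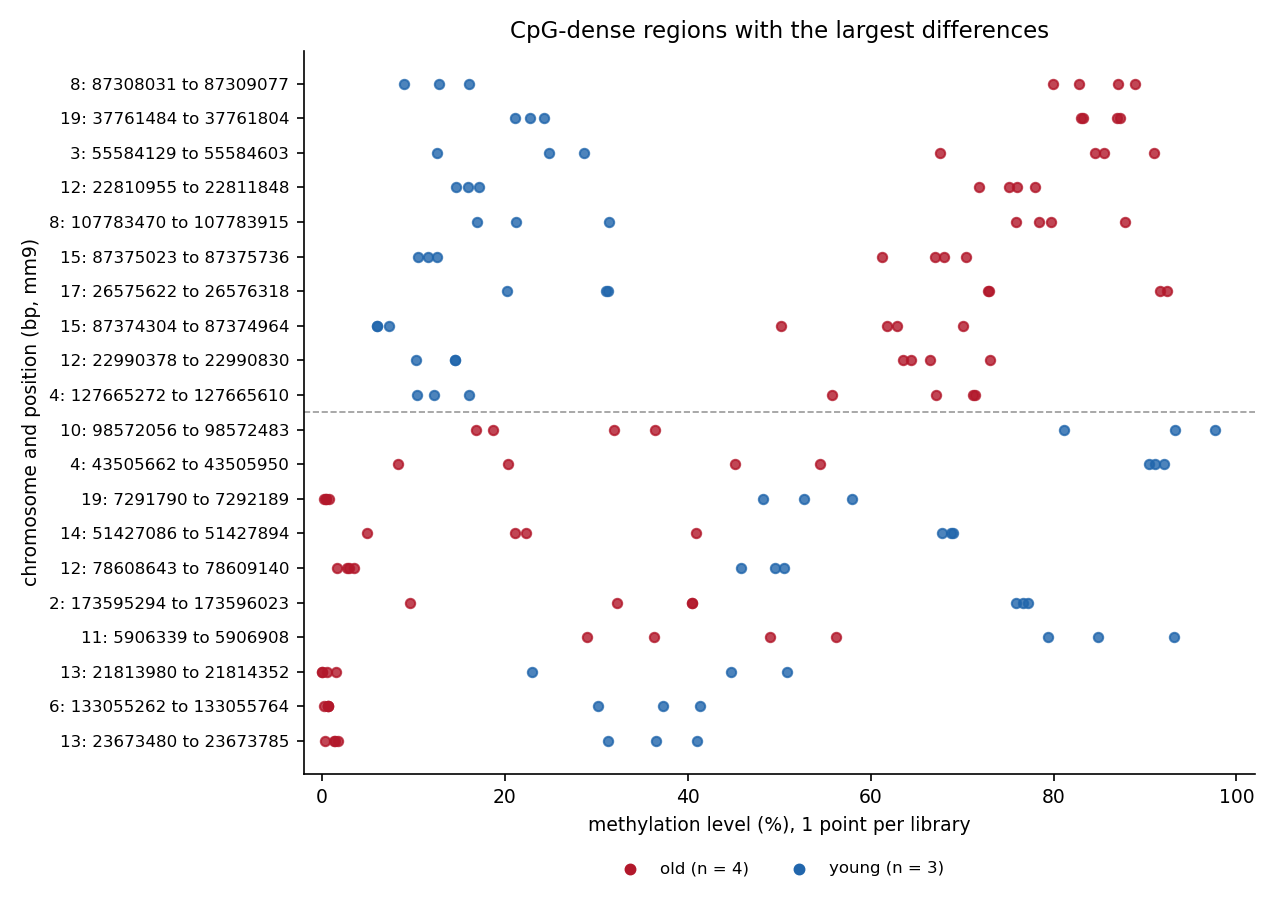
Methylation level (x axis, percent) of the 20 named CpG-dense regions (y axis, chromosome and position in bp, mm9), with a point per library, old (n = 4) and young (n = 3). The 10 regions above the dashed line were higher and the 10 below it lower in old libraries, and in none do the groups overlap.

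**Figure D5:**
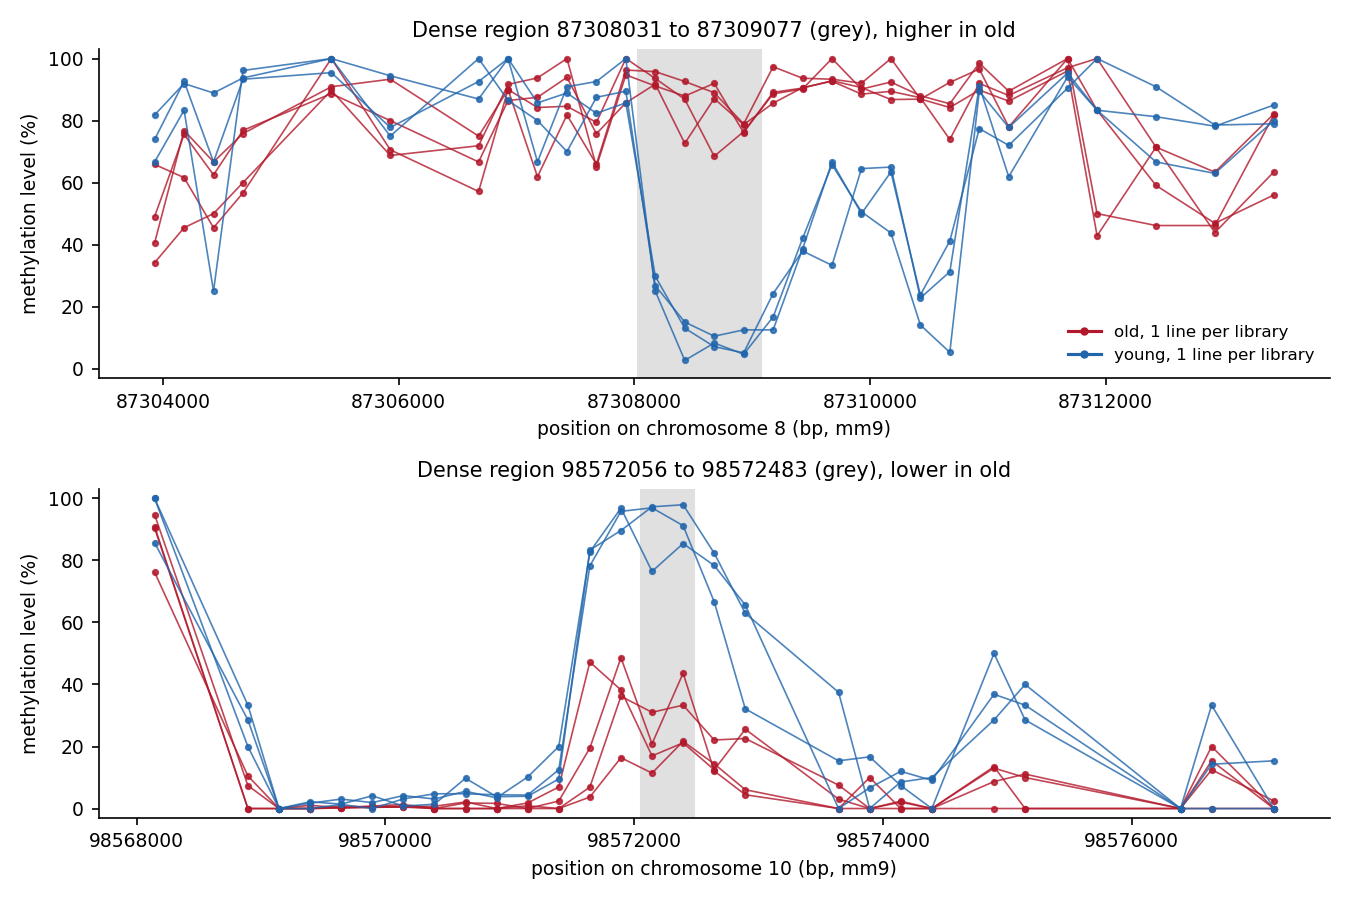
Methylation level (y axis, percent) in bins of 250 bp over 5000 bp on either side (x axis, bp, mm9) of the dense regions with the greatest gain, on chromosome 8, and the greatest loss, on chromosome 10. Each line is a library, the shaded part is the region, and bins with under 5 reads in a library are left out; within the region on chromosome 8 the old libraries are at 84.7% and the young at 12.6%.

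Called 1 kb tiles were mostly lower in old libraries. Of 927104 tested tiles, 26869 were called, 16849 lower and 10020 higher. The groups did not overlap in 139829 of the tested tiles, where chance gives 5.71% of them, and 24776 of these were called. Tiles that overlap an autosomal dense region went the other way, with 1884 higher and 358 lower, whereas those over 10 kb away had 5679 higher and 11686 lower. On the X chromosome 602 tiles were higher and 65 lower. Autosomal tiles called lower had a median level of 64.7% in young and 42.2% in old libraries, and a median size of difference of 18.9 points. Those called higher had median levels of 55.7% and 77.7%, and a median difference of 17.8 points. The balance of calls changed with the correction: with the mitochondrial level modelled 10241 tiles were higher and 5379 lower, and with the level at dense regions under 5% modelled 10344 were higher and 11117 lower. The 16849 tiles called lower as deposited kept a mean difference of -18.1 and -19.2 points, against -19.8. Of the 11470 lost with the mitochondrial level 11420 lost the call by adjusted p. Without young replicate 1, 2 or 3 the count was 13364, 15683 or 14186, and limma on logit levels called 4581.

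Among named tiles away from dense regions, chromosome 10 from 39978001 to 39979000 was at 4.78% ± 4.28 (SD, n = 4) in old and 75.3% ± 3.23 (SD, n = 3) in young libraries, the greatest loss of all (adjusted p = 3.42e-28, quasi-binomial model with limma). Tiles on chromosome 5 from 93285001 to 93286000 (7.02% against 66.2%) and chromosome 7 from 135137001 to 135138000 (2.75% against 60.6%) were also nearly unmethylated in old libraries. Losses on chromosome 15 included 3 tiles within the stretch from 74762001 to 74788000, at 28.4%, 33.5% and 18.1% in old against 85.7%, 89.9% and 77.1% in young libraries. Losses close to a dense region lay on chromosome 9 from 64022001 to 64023000 (8.04% against 70.5%) and from 78326001 to 78327000 (20.0% against 80.3%). Nearer still was a tile on chromosome 3 from 108338001 to 108339000, at 14.5% ± 7.77 (SD, n = 4) in old libraries, a difference of -60.5 points from the young ones. With the mitochondrial level subtracted from the reads this tile and those from 74776001 on chromosome 15 and 43505001 on chromosome 4 were no longer called (adjusted p = 0.0659, 0.0739 and 0.0841, quasi-binomial model with limma), with differences of -60.7, -58.0 and -59.7 points. A tile on chromosome 3 from 50234001 to 50235000 was at 19.3% against 78.9%, and the tiles from 43505001 on chromosome 4 and from 98572001 on chromosome 10 overlap dense regions named above.

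Of the 12 tiles named for a gain, 9 overlap dense regions. The tile on chromosome 5 from 144015001 to 144016000, with 154 CpG sites, was at 90.7% ± 2.17 (SD, n = 4) in old and 26.8% ± 3.20 (SD, n = 3) in young libraries, and that on chromosome 7 from 64764001 to 64765000 at 68.0% against 13.8%. Others lay on chromosome 12 from 22510001 to 22511000 (81.6% against 26.9%), chromosome 4 from 145617001 to 145618000 (70.0% against 14.2%) and chromosome 3 from 98624001 to 98625000 (93.1% against 38.0%). The tile on chromosome 4 was no longer called with the mitochondrial level subtracted from the reads (adjusted p = 0.0790, quasi-binomial model with limma), at a difference of 61.4 points. The tiles from 87308001 and 87309001 on chromosome 8, 22811001 on chromosome 12 and 55584001 on chromosome 3 overlap named dense regions. Far from any dense region were tiles on chromosome 3 from 37831001 to 37832000 (91.0% against 20.3%), chromosome 5 from 28874001 to 28875000 (92.1% against 34.8%) and chromosome 2 from 141366001 to 141367000 (83.5% against 27.6%), with as few as 28, 21 and 20 reads in a library.

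The median of all 7 libraries rests on more old libraries than young ones, and the distance from it also depended on depth. Over tiles the mean distance was 3.84 points ± 0.246 (SD, n = 4) in old and 4.76 points ± 0.0895 (SD, n = 3) in young libraries, without overlap (two-sided exact permutation p = 0.0286). With all libraries thinned to the shallowest the difference was 0.0689 points (exact permutation p = 0.8). The mean distance to other libraries of the same group was then greater in old libraries, by 0.642 points. Libraries of a group share the pairs behind these distances, so that the permutation test does not hold for them and no p-value is given.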

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

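The tests of unconverted cytosines and the removal of variant sites were chosen after the results they bear on had been seen; the tests of depth, site choice and other splits of the samples were not.

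Of the 35 splits of the 7 libraries into 4 and 3, only 1, the real one, gave as many called dense regions (2857, against 577 in the highest other split). Only 1 gave as many called tiles (26869, against 4625). A share of 1 in 35 is the smallest these splits can give. Every other split mixes old and young libraries, which widens the spread within its groups and lowers its count. The splits thus do not show how many calls chance alone would give, and depth and the unconverted share follow the real split. The highest other split in both cases put old replicate 4 with the 3 young libraries.

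Called CpG-dense regions were mostly higher in old libraries, in 2517 of 2857 (88.1%). The old libraries have the lower mitochondrial level, and unconverted reads in young libraries would act in the opposite direction. The share depended on the minimum difference: without it 12874 regions passed, 2734 higher and 10140 lower (21.2% higher). Over all tested dense regions the median difference was -1.61 points. Modelling the mitochondrial level raised the mean gain of the 2517 regions from 16.6 points (spread between libraries 1.25) to 20.7 points. This rise decides nothing, since the correction lowers young levels more than old ones wherever old ones are higher. Of these regions 1095 lost the call, all by adjusted p, while the median dispersion of the 2517 rose from 1.99 to 4.02. The denominator degrees of freedom fell from 15.2 to 10.4. The bound written for this test, at least as many regions called higher, was missed, with 1530. With all libraries thinned to the same total of reads 2509 regions were called higher, but random thinning cannot move the expected level of a region, so that this does not address depth. Without likely variant sites 99.3% of the called regions kept their call and direction, and the chromosome with the most calls held 10.9% of those called higher. The calls kept without likely variant sites speak against variants as the cause of the gain. The direction of the gain speaks against unconverted reads as its cause at the 2517 regions called higher, although the written bound was missed. The 10140 regions lower without a minimum difference go in the direction that unconverted reads would give. Age, depth and a batch that follows age cannot be told apart, since all of them follow the groups.

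Isolated sites were lower in old libraries, by a difference of -2.88 points, and here unconverted reads in young libraries act in the direction of the pattern. After correction for the mitochondrial level -1.61 points remained (spread between libraries 0.758, exact permutation p = 0.0857) with overlap of the groups, which ended the call. After correction for the floor at unmethylated dense regions -2.39 points remained without overlap (exact permutation p = 0.0286). Together these values argue against unconverted reads as the whole cause only if isolated sites held no greater unconverted share than the sequence used for correction. The rule behind this reading was settled after the values were seen, when a demand for an exact p under 0.05 was dropped. Over isolated sites with at least 5 reads in every library, weighted equally, the difference was -2.80 points (spread between libraries 0.683, exact permutation p = 0.0286, Benjamini-Hochberg p = 0.0571), which missed the adjusted threshold but argues against a different choice of sites. With all libraries thinned it was -2.88 points, but random thinning cannot move a mean weighted by reads, so that this does not address depth. A share of the difference from incomplete conversion, depth, a batch that follows age and age itself stay open, since conversion at isolated sites was not measured on its own.

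Dense regions with a mean level under 5% over all libraries had a higher floor in young libraries than in old ones, of 3.01% against 1.02%. The mitochondrial level differed in the same direction, by -4.89 points (old minus young), in every library, and could have overlapped but did not. This is consistent with more unconverted cytosines in the young libraries, while mitochondrial and nuclear levels differ in size, so that neither is an exact measure of the other. A true difference in methylation at these regions was not tested.

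In 4 of 79 groups of old libraries a sample stood far from the other 3, where chance gives about 3.95. At the 16 X-linked dense regions under 5%, old replicate 4 was at 1.65%, the others between 0.962% and 1.05%. In the distance from the median of all libraries old replicate 1 was at 4.21 points, the others between 3.67 and 3.76. On the Y chromosome with its unplaced part old replicate 4 was at 67.2%, the others between 67.9% and 68.0%. At the tile on chromosome 15 from 74787001, old replicate 4 was at 5.71%, the others between 21.8% and 22.5%.

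A difference also appears in sequence that the comparisons left out. On unplaced contigs the level was 64.8% ± 0.354 (SD, n = 4) in old and 59.2% ± 0.638 (SD, n = 3) in young libraries, a difference of 5.53 points (two-sided exact permutation p = 0.0286). Reads per site there were 8.49 to 9.24 in old and 8.58 to 9.15 in young libraries, against 6.66 to 7.42 and 3.57 to 4.06 over all listed sites. The groups may thus hold a different mix of reads on these contigs, which was not tested. On the Y chromosome with its unplaced part it was 67.8% ± 0.379 (SD, n = 4) against 60.6% ± 0.408 (SD, n = 3), a difference of 7.21 points (two-sided exact permutation p = 0.0286). Only 1669 to 2132 sites per library were listed on the Y chromosome itself, and whether these reads stem from it was not tested.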

How the results depend on the processing

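Chosen after the data were seen were all corrections for unconverted reads in both forms, the removal of variant sites, the spread within groups and the read-weighted density classes over sites with at least 5 reads; all other alternatives were planned. Of 1322 alternative values 1266 kept the direction and the side of the threshold where that side was tested, or the size of the count. For class levels with a library left out the threshold was not tested. The smallest exact permutation p is then 0.1 without an old library and 0.0667 without a young one. Of 928 values for named regions none reversed and 9 lost the call, all by adjusted p under a correction for unconverted reads, with differences about as large as before.

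Leaving out a library gave a global difference of -1.02 to -0.510 points, -3.22 to -2.55 at isolated sites, 2.26 to 2.46 at sites with 6 or more neighbours and 8.77 to 9.37 at X-linked dense regions. Called dense regions ranged from 2460 to 3004. Called tiles ranged from 13364 to 29233, with 13364, 15683 and 14186 without young replicates 1, 2 and 3.

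Replicate numbers did not pair the libraries (correlations of deviations from -0.0158 to 0.00026). With the replicate block there were 2877 called dense regions and 25777 called tiles.

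The coverage minimum moved the class levels. The global difference was -1.44 points over sites with at least 5 reads, equally weighted, -1.85 points read-weighted, and 2.74 points over the 14960 sites with at least 10 reads. Over sites with at least 5 reads the differences, equally weighted and read-weighted, were -2.80 and -2.94 at isolated sites, -0.567 and -0.363 with 3 to 5 neighbours, and -0.199 and 0.122 with 6 or more. The cause was not tested. With equal weight per tile the classes under 10%, at 10 to 50% and at 50 to 80% passed the adjusted threshold, at -2.42, -3.82 and -2.61 points. Thinned, the differences at isolated sites, with 3 to 5 and with 6 or more neighbours were -2.88, 1.18 and 2.35 points, and all 3 missed the adjusted threshold, as the exact p with 3 to 5 neighbours rose to 0.0571. The spread reversed to 0.0689 points when thinned and to 0.642 points within groups.

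Correction for the mitochondrial level reversed the global difference (0.886), sites with 1 to 2 neighbours (0.298), the tile classes under 10% (3.07), at 10 to 50% (1.55) and at 80% or more (0.336), dense regions under 5% on autosomes (3.17) and the X chromosome (2.91), whose levels it put below 0 in both groups, and sites in the 2 nearer classes of distance beyond 500 bp from a dense region (0.948 and 0.0928). It gave -1.61 points at isolated sites, 2.88 with 3 to 5 neighbours and 6.82 with 6 or more, which missed the adjusted threshold. Dense regions at 5 to 10% passed it, at 6.81 points, and at 3.70 points after correction for the floor of dense regions under 5%. That correction left -0.0034 points at autosomal regions under 5%, by its construction, -0.251 at X-linked ones and -2.39 at isolated sites.

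Tile counts moved to 15620 with the mitochondrial level modelled (10241 higher, 5379 lower) and to 1458 with it subtracted from the reads (1217 higher, 241 lower), while the floor gave 21461 modelled (10344 higher, 11117 lower) and 10047 subtracted (5413 higher, 4634 lower). The 16849 tiles first called lower had mean differences of -18.1 and -19.2 points in the modelled forms, against -19.8, while 11470 and 5733 of them lost the call. Dense regions moved to 1558 with the mitochondrial level modelled (1530 higher, 28 lower) and 1942 with it subtracted (1894 higher, 48 lower), and the floor gave 2612 modelled (2486 higher, 126 lower) and 1528 subtracted (1451 higher, 77 lower). The modelled form, chosen after the counts of the other were seen, keeps more tiles but, with the mitochondrial level, fewer dense regions; these stayed mostly higher in each form. Tiles were 4581 with limma on logit levels and 8881 at 5 kb. Dense regions were 12874 with no minimum difference, which turned the balance of calls (2734 higher, 10140 lower). They were 1546 with gaps of 100 bp and 40 sites (1376 higher, 170 lower).

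Promoters, gene bodies and gene lists were not run, for want of an annotation of the same build. Small differences can remain uncalled at these depths, which were lower in the young libraries.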

Other observations

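The tests below on clusters, the X chromosome and isolated sites by window were set before their results were seen, while the matching of clusters by level, the correction of the 1 Mb windows, the groups of neighbouring regions and the rest were chosen afterwards.

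Called dense regions lay in groups on some chromosomes. On chromosome 18 from 37089827 to 37181875, 20 neighbouring regions were called, all higher in old libraries, with a mean gain of 18.3 points, and 13 more lay from 37879972 to 37928161, with a mean gain of 27.4 points. Chromosome 2 from 74493497 to 74537368 held 14 regions, all higher, by 13.5 points on average. The X chromosome held 12 from 11704787 to 11737699, with a mean gain of 16.2 points, and chromosome 15 held 10 from 102740565 to 102798093, all higher. The reverse was seen on chromosome 13 from 23623211 to 23673785, where 6 regions were all lower, with a mean difference of -18.7 points. Neighbouring regions within 20 kb of each other were joined.

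Windows of 1 Mb were mostly lower in old libraries. Of 2141 windows 1821 were lower and 320 higher, with a median difference of -1.26 points and a range of -4.57 to 7.81. In 1150 windows all old libraries lay below all young ones and in 76 above, where chance gives 2.86% in each direction. After correction for the mitochondrial level 1059 windows were lower and 1082 higher, with a median of 0.00887 points, and after correction for the floor 1658 were lower and 483 higher, with a median of -0.779 points.

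Regions in clusters were tested for a greater gain. At autosomal dense regions with a level of 5 to 75%, the gain was 9.80 points with no other dense region within 10 kb, 7.88 points with 1 to 2 and 8.19 points with 3 or more. The difference between the last and the first was -1.61 points (spread between libraries 1.22), but the sets differ in level, at 19.5% and 13.7% in young libraries. With regions without others weighted to the levels of those with 3 or more, in bins of 5 points, their gain was 7.94 points, and the difference was 0.256 points, less than the spread between libraries, so that a small effect of clustering stays open.

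X-linked regions were tested for a gain equal to that of autosomal regions of like level. At 25 to 75% the gain of X-linked regions was smaller by a difference of -5.57 points, and by -7.72 points (10.6 against 18.3) when autosomal regions were matched in bins of 5 points. Classes and bins rest on the mean of all 7 libraries, which holds the gain itself. In young libraries the matched sets were at 29.3% on the X chromosome and 24.8% on the autosomes. A gain can place a region in a class, so that these comparisons do not settle whether gains differ at a like starting level. Compared afterwards, the X-linked gain at 10 to 25% was 8.20 against 9.62 points, a difference of -1.42 points that is close to the spread between libraries (1.46 on the X chromosome, 1.33 on the autosomes) and leaves an equal gain open in this class. At 75% or more the X-linked gain was greater, at 4.56 against 2.78 points, a difference of 1.78 points (spread between libraries at most 0.213). The share called higher was 47.1% on the X chromosome and 63.3% on the autosomes at 25 to 75%, and 23.0% and 16.1% at 75% or more.

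A loss at isolated sites concentrated in windows of low methylation was not seen. The difference in the windows of lowest level (597 or 598 of them) minus that in as many of highest level was 0.196 points (less than the spread between libraries), 0.251 after correction for the floor and 0.337 after correction for the mitochondrial level.

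The sex chromosomes were read at like depth in all libraries of a group. Reads per site on the X chromosome over those on the autosomes were 0.780 to 0.810 in old and 0.720 to 0.746 in young libraries, and the Y chromosome took 46.6 to 49.0 of every 1000000 reads in old and 53.8 to 56.6 in young libraries. On the opposite strand the share of reads other than G was 0.729% to 0.755% in old and 0.510% to 0.552% in young libraries.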
